A study of Arabidopsis thaliana with 48 samples.

How the data were processed

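Expression of seedlings in 16 groups of 3 arrays (8 conditions at 45 min and at 4 h) was measured on ATH1 arrays, each with 22810 probe sets. The values analysed are the linear intensity values as deposited by the authors, which were made with MAS5 per the submitters' processing notes (version not given in the sources used here). Each array's trimmed mean lies near 100 in the values themselves, as a scaling of arrays to a common level gives, and no further scaling was applied in the main setting. Values of 0 occur and no detection calls were used here, so that low signals near the floor are uncertain and changes between such signals are sensitive to the pseudocount. A scaling to a common mean assumes that total expression is alike between arrays. The number of arrays limits the precision.

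Groups and replicate numbers were taken from the sample labels, and all 48 arrays were kept. Some labels disagree with each other. The description of UV-A/B 45 min replicate 2 gives darkness while its title gives UV-A/B, and the protocol of dark 4 h replicate 1 gives green rather than red germination light. The title of far-red 45 min replicate 2 gives the number 1 in a prefix and the number 2 at its end, and the latter was used. The deviations of this array correlated at 0.33 and 0.463 with those of replicate 2 of darkness and of red light at 45 min, against medians of -0.143 and -0.176 between different numbers in these comparisons. In 5 of 6 UV-A/B labels the light treatment is not spelled out. Counts were also computed without the first 2 of these arrays, a choice made after the data were seen. Without far-red 45 min replicate 2, which is among the arrays left out in turn, 254 probe sets were called for far-red against dark at 45 min and 18 for red against far-red light, where its number enters the block.

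The values were log2 transformed after adding a pseudocount of 1, which understates the change of low genes. Probe sets above the 40th percentile of an array in at least 3 arrays were tested, and 64 control probe sets were left out, which leaves 15777. The 16 group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) over all 48 arrays, which gives 32 residual degrees of freedom and a mean prior of 6.15. Adjusted p-values are Benjamini-Hochberg values within a contrast, and a probe set is called where the adjusted p is under 0.05. There were 30 contrasts: 14 of a light treatment against the dark group of its harvest, 8 between light treatments, 7 of the 4 h effect against the 45 min effect, and 1 between the dark groups. Tables were handled with data.table (version 1.17.8) and pandas 2.3.3 (Python 3.11.15, numpy 2.4.6), and figures were drawn with matplotlib 3.10.9.

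Probe sets were named from the given table of probe set genes, with symbols taken from a RefSeq gene table by locus. Of the 22746 probe sets without controls, 13513 have 1 gene, 503 have several and 8730 are not listed, and the last 2 kinds were not named. Of the 13513, 13436 matched by locus. Of the genes, 1595 have a symbol other than the locus. A list's members are measured only where a probe set of theirs is named and passes the filter.

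Before the data were examined, 23 gene lists of light biology, the main test, a 10-gene panel, the rule for named genes and the alternatives were fixed. On 4 of the lists (photoreceptors, DNA repair and damage response, nitrogen assimilation, and seed storage and late embryogenesis) no gene had a named probe set, and of the other 19 lists 4 had at least 5 measured members. These 4 were tested with camera (inter-gene correlation 0.01, with an estimated correlation as an alternative), with Benjamini-Hochberg adjustment over lists and contrasts in each family of contrasts (56 tests for the light against dark family). The other lists were read member by member. Named probe sets were found for 5 of 26 photosystem, 6 of 18 chlorophyll, 5 of 18 flavonoid and 7 of 21 cell wall members. For light harvesting this held for 3 of 20 members and for the clock for 1 of 19, so most members are not covered. None of the 10 panel genes had a named probe set, so a panel of 10 other genes was put in its place (9 of them pass the filter), and 23 further lists were made from the annotation's symbols and loci, of which 22 could be tested (308 tests in the light against dark family). Both were chosen after the annotation was seen and before any expression result. A list of ribosomal proteins was left out because the annotation holds no descriptions.

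In each contrast named genes were selected by a fixed rule, and the text gives a part of them: the 4 called members of each list with the largest change and all members of lists of 5 or fewer, the 8 largest rises and 6 largest falls among called probe sets of 1 gene whose light and dark arrays do not overlap, and the panel. For contrasts of effects between harvests the condition on overlap is not defined and was not applied. A gene with several probe sets is given by the one with the highest mean signal. Genes outside the rule were chosen after their values were seen, as were the 6 genes plotted.

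The alternatives were quantile normalization, a pseudocount of 16, no filter, a filter at the 60th percentile, the replicate number as a block, a fit on the groups compared alone, and leaving out each array in turn. Whether replicate numbers pair arrays was decided by the correlation of the arrays' deviations from their group means: numbers pair where all 3 pairs of a contrast exceed 0.1, which held in 12 of 23 contrasts. A time difference was taken as paired where both of its comparisons with darkness were, which held for UV-A/B, a rule set after blocked calls had been seen. Over all arrays the median correlation was 0.165 for equal numbers, where 80.3% of pairs exceed 0.1, and -0.083 for different ones. The first principal component of the deviations held 19.2% of their variance, with an R2 of 0.825 on the replicate number. The second held 8.45%, with an R2 of 0.694. Replicate numbers thus mark a structure over all arrays, also where a contrast fails the rule. The main fit, from which the main counts and p-values come, leaves this structure out. The rule was applied mechanically, although blocked counts had been seen in an exploratory run before. Effects of contrasts that share dark arrays were set against simulations of unchanged groups.

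The test was checked on data simulated for the far-red 45 min comparison over 15777 probe sets, 50 of them changed by each of 4 folds. The spread of each probe set was taken from all 48 arrays around their group means, not from the far-red comparison alone. Noise was drawn independently, so effects shared by arrays of equal replicate number were left out. The rates below therefore need not hold for the real comparison. At 1.5-fold 28% were recovered, at 2-fold 92%, at 4-fold 90% and at 8-fold 96%, with 5 false calls. In such data small changes are often missed with 3 arrays per group.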

Results

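Gene expression was measured on 48 ATH1 arrays of dark-grown Arabidopsis thaliana Col-0 seedlings, mainly hypocotyl and cotyledons, that were exposed to 1 of 7 light treatments or kept in darkness. Seedlings had grown for 94 h in darkness at 22 °C before the onset of light. The 7 treatments were continuous far-red (715 nm), red (650 nm), blue (453 nm) and white light at 10 µmol per m2 and s, a red pulse of 1 min at 50 µmol per m2 and s, and pulses of 5 min at 7 W per m2 of UV-A light (filter cut-off 327 nm) or of UV-A and UV-B light (cut-off 307 nm in the 1 of 6 labels that gives the treatment, called UV-A/B here). Each treatment and the dark control were harvested at 45 min and at 4 h, which gives 16 groups of 3 arrays. The number of arrays limits the precision. The labels do not say whether the 3 replicates of a group came from separate cultures, so that p-values measure the spread between these arrays, which may be technical.

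Signals of replicates correlated across probe sets with r between 0.9504 and 0.9804 (median 0.9704), against a median of 0.9447 between arrays of different groups. The highest value between groups was 0.9825, so that the ranges overlap. These correlations are across probe sets, which are not independent replicates. Of the 15777 probe sets tested, 8612 each stand for 1 named gene, and the counts below are of probe sets. Changes are log2 differences of signal + 1 with their standard error, each group mean is a linear MAS5 signal with its SD over n = 3 arrays, and adjusted p-values come from limma with the Benjamini-Hochberg method. A gene is called higher or lower where that adjusted p is under 0.05. Arrays named below as left out were each left out alone, unless 2 are joined by "and".

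**Figure D1:**
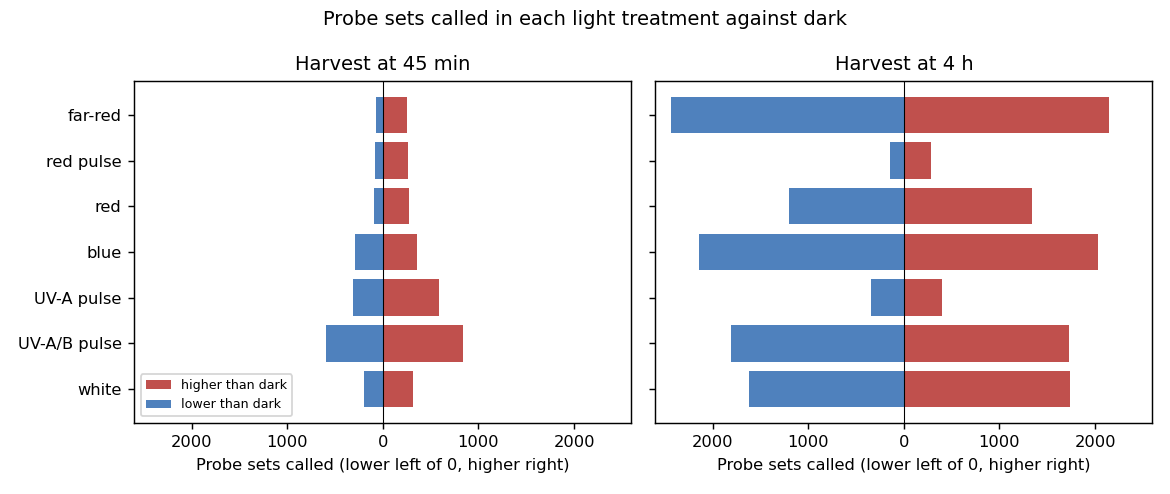
Probe sets called by limma at an adjusted p under 0.05 in each light treatment against the dark group of the same harvest, with those lower than dark drawn left of 0 and those higher drawn right of 0. At 4 h the far-red bar holds 4584 probe sets and the red pulse bar 430, and at 45 min the longest bar is that of the UV-A/B pulse with 1426.

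After 45 min of light the transcription factor gene HYH, a homologue of HY5, was higher than in darkness in each of the 7 treatments. In far-red light its signal was 21.7 ± 4.35 against 1.93 ± 1.19 in darkness, a log2 change of 3.01 ± 0.38 (SE) with adjusted p = 3.51e-07. Both means lie under the 40th percentile of these arrays (27.2 to 28.3), the level used in the filter, so the size of this change is uncertain. AT5G58750 rose by 3.97 ± 0.39 (SE) from a low dark signal of 2.63 ± 1.12, and AT3G02910 by 2.73 ± 0.17 (SE) from 127 ± 39.7. The clock gene GI rose by 1.24 and UGT78D2, a flavonol and anthocyanidin glucosyltransferase, by 1.81. IAA29, an Aux/IAA gene, fell to 30.3 ± 4.85 from 106 ± 14.4, a change of -1.77 ± 0.18 (SE), and AT1G77200 changed by -1.98. In all, 329 (253 higher and 76 lower) probe sets were called in far-red light at 45 min. A fit on the 2 groups alone called 179. The log2 change with a pseudocount of 16 was -1.21 for AT1G77200, 1.92 for AT5G58750 and 1.07 for HYH (far-red). The call of AT1G77200 was lost without dark 45 min replicate 3 or far-red 45 min replicate 2 (adjusted p = 0.0608 and 0.226).

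Red light at 45 min was given either as a 1 min pulse followed by darkness or without interruption. HYH rose by 2.94 ± 0.38 (SE) after the pulse and by 2.71 ± 0.38 (SE) in continuous red, and AT5G58750 rose by 2.90 and 3.32. CCR2, named for cinnamoyl-CoA reductase, rose by 2.08 and 2.45, and AFR, an F-box gene of far-red signalling, by 1.92 and 1.97. EXO fell by 1.59 after the pulse and by 1.58 in continuous red on the log2 scale, and IAA29 changed by -1.71 and -1.77. The pulse called 348 (264 higher and 84 lower) probe sets and continuous red 368 (274 higher and 94 lower). With the replicate number as a block, the pulse called 532. Fits on the 2 groups alone called 197 for the pulse and 214 for continuous red. A pseudocount of 16 gave a log2 change of 1.44 for AT5G58750 (red), 1.16 for AT5G58750 (red pulse), 1.00 for CCR2 (red), 0.86 for CCR2 (red pulse), 0.91 for HYH (red) and 1.03 for HYH (red pulse).

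GH3.3 and HAT2 fell in blue and in white light at 45 min. GH3.3, which encodes an enzyme that conjugates auxin to amino acids, changed by -1.41 ± 0.23 (SE) in blue and -1.20 ± 0.23 (SE) in white, and HAT2, a homeodomain gene, by -1.33 and -1.34. BZIP34 changed by -2.76 in blue and by -3.21 in white light. AT3G02910 rose by 2.97 and 2.83, HYH by 3.27 and 2.47, and GI by 1.38 and 1.54. Blue light called 643 (357 higher and 286 lower) probe sets and white light 521 (320 higher and 201 lower), and fits on the 2 groups alone called 406 and 303. With a pseudocount of 16 the log2 change was -1.16 for BZIP34 (blue), -1.24 for BZIP34 (white), 1.23 for HYH (blue) and 0.81 for HYH (white).

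At 45 min after the UV pulses AT5G48570, which encodes an FK506-binding protein, rose by 2.90 ± 0.53 (SE) after UV-A and by 2.84 ± 0.53 (SE) after UV-A/B, with signals of 181 ± 114 and 215 ± 183 against 19.9 ± 7.37 in darkness. AT5G51440 rose by 2.87 and 3.6, and the small heat shock protein gene AT2G29500 by 1.81 after UV-A/B, while its change of 1.3 after UV-A had adjusted p = 0.0879. The third measured member of the heat shock list, ATHSP22.0, changed by 0.25 and 0.19 (adjusted p = 0.725 and 0.727). After the red pulse AT5G51440 (1.69, adjusted p = 0.0366), the co-chaperone gene Hop3 (1.74, adjusted p = 0.00604) and AT2G20560 (1.77, adjusted p = 2.07e-06) were also called higher, while AT5G48570 changed by 1.18 (adjusted p = 0.421). In continuous red light Hop3 (1.43, adjusted p = 0.0382) and AT2G20560 (1.47, adjusted p = 6.79e-05) were called higher as well, and AT2G20560 in white light (1.19, adjusted p = 0.00112). The change of AT5G51440 after the red pulse was 1.03 with a pseudocount of 16. THI2.2, a thionin gene, rose by 3.08 and 3.24. Of the 3 measured genes of rapid wound and stress responses, WRKY6 rose after both pulses (by 1.06 and 1.41), while WRKY53 and STZ rose after UV-A/B by 1.46 and 0.84 and had adjusted p = 0.967 and 0.226 after UV-A. Compared directly between UV-A/B and UV-A, WRKY53 differed by 1.515 (adjusted p = 0.00103), while the difference of 0.434 for STZ was not called (adjusted p = 0.288). UV-A called 899 (584 higher and 315 lower) probe sets and UV-A/B 1426 (835 higher and 591 lower), and fits on the 2 groups alone called 482 and 785. The log2 change with a pseudocount of 16 was 1.64 for THI2.2 (UV-A) and 1.80 for THI2.2 (UV-A/B). The log2 change was 0.94 for AT2G29500 (UV-A/B) without UV-A/B 45 min replicate 1. The fit with the replicate number as a block also called AT2G29500 (UV-A) (adjusted p = 0.0331). AT2G29500 (UV-A) was called without UV-A 45 min replicate 3 (adjusted p = 0.0109). The call of AT2G29500 (UV-A/B) was lost without UV-A/B 45 min replicate 1 (adjusted p = 0.171). The call of AT5G51440 (red pulse) was lost with a pseudocount of 16 (adjusted p = 0.0725) and without dark 45 min replicate 2 or 3 or red pulse 45 min replicate 1, 2 or 3 (adjusted p = 0.216, 0.0709, 0.129, 0.0781 and 0.0971). The call of Hop3 (red) was lost with a pseudocount of 16 (adjusted p = 0.113) and without dark 45 min replicate 2 or 3 or red 45 min replicate 1, 2 or 3 (adjusted p = 0.105, 0.252, 0.132, 0.179 and 0.0555). The call of Hop3 (red pulse) was lost without dark 45 min replicate 3 (adjusted p = 0.0691). The call of WRKY6 (UV-A) was lost without dark 45 min replicate 2 or UV-A 45 min replicate 3 (adjusted p = 0.0605 and 0.0727).

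After 4 h of far-red light THI2.2 was at 929 ± 55.7 against 6.73 ± 3.48 in darkness, a log2 change of 7.00 ± 0.62 (SE) with adjusted p = 5.83e-12. CHIL, a chalcone isomerase-like gene, rose by 5.50 ± 0.44 (SE), MSRB6, a methionine sulfoxide reductase gene, by 5.31, HYH by 4.86 and AT3G52740 by 4.87. GH3.3 changed by -3.36 ± 0.23 (SE) and the xyloglucan-modifying gene XTH19 by -3.16 ± 0.14 (SE). PORB, one of the light-dependent protochlorophyllide oxidoreductases, fell by 1.55 on the log2 scale, and AT1G72290, of the Kunitz inhibitor family, was at 1.67 ± 0.513 against 60.4 ± 10.1, a change of -4.53. Far-red light called 4584 (2150 higher and 2434 lower) probe sets at 4 h. With a pseudocount of 16 the log2 change was -2.1 for AT1G72290, 2.35 for AT3G52740 and 3.03 for HYH.

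Blue, white and red light at 4 h also raised THI2.2, by 6.94, 6.82 and 6.27, and MSRB6, by 4.83, 4.38 and 2.98. CHIL rose by 4.43 ± 0.44 (SE) in blue, 4.31 ± 0.44 (SE) in white and 2.13 ± 0.44 (SE) in red light. The Calvin cycle genes RCA, for rubisco activase, and SBPASE, for sedoheptulose bisphosphatase, rose by 1.96 and 1.45 in blue, 2.0 and 1.25 in white, and 1.89 and 1.03 in red. PORB changed by -1.13 in blue and -1.01 in white, and its change of -0.35 in red had adjusted p = 0.516. AT1G72290 showed log2 changes of -4.53, -4.61 and -4.26. Blue light called 4169 (2026 higher and 2143 lower) probe sets, white light 3355 (1738 higher and 1617 lower) and red light 2541 (1339 higher and 1202 lower). The log2 change with a pseudocount of 16 was -2.1 for AT1G72290 (blue), -2.06 for AT1G72290 (red), -2.12 for AT1G72290 (white), 2.70 for CHIL (blue), 0.98 for CHIL (red) and 2.59 for CHIL (white). The call of PORB (white) was lost without dark 4 h replicate 2 (adjusted p = 0.0568). The call of SBPASE (red) was lost without dark 4 h replicate 1, 2 or 3 or red 4 h replicate 1, 2 or 3 (adjusted p = 0.147, 0.0552, 0.114, 0.0901, 0.131 and 0.082).

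The red pulse and the UV-A pulse had fewer called probe sets at 4 h than the continuous treatments. THI2.2 rose by 5.06 ± 0.62 (SE) after the red pulse and 4.87 ± 0.62 (SE) after UV-A, AT5G48490 by 3.63 and 3.05, and PSAE-1, a subunit of photosystem I, by 2.39 and 2.21. COR27 changed by -1.26 and -1.36 and AT1G72290 by -4.40 and -4.22. For HYH the changes of 1.19 and 1.15 had adjusted p = 0.0913 and 0.0753. A block on the replicate number called HYH in both (adjusted p = 0.043 and 0.0381), although the numbers do not pair these arrays by the rule. The red pulse called 430 (285 higher and 145 lower) probe sets, which became 274 without dark 4 h replicate 1, 229 without dark 4 h replicate 3, 277 without red pulse 4 h replicate 1, 223 without red pulse 4 h replicate 3, and 717 in a fit on the 2 groups alone. UV-A called 742 (402 higher and 340 lower), which became 474 without dark 4 h replicate 1, 463 without dark 4 h replicate 3 and 409 in a fit on the 2 groups alone. Both counts rose with the replicate number as a block, as given in the part on processing. The label of dark 4 h replicate 1 gives green rather than red germination light, and without it and UV-A/B 45 min replicate 2 the counts were 266 and 471. A pseudocount of 16 gave a log2 change of -2.09 for AT1G72290 (red pulse) and -2.06 for AT1G72290 (UV-A). HYH (red pulse) was called without dark 4 h replicate 1 (adjusted p = 0.0138). HYH (UV-A) was called without dark 4 h replicate 1 (adjusted p = 0.0115). The call of COR27 (red pulse) was lost without dark 4 h replicate 1, 2 or 3 or red pulse 4 h replicate 1 or 3 (adjusted p = 0.0516, 0.113, 0.106, 0.244 and 0.0835). The call of COR27 (UV-A) was lost without dark 4 h replicate 2 or UV-A 4 h replicate 1 (adjusted p = 0.052 and 0.0806).

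At 4 h after the UV-A/B pulse both measured members of the oxidative stress list rose, as did UGT84A1. UGT84A1, a hydroxycinnamate glucosyltransferase gene, was at 131 ± 16.6 against 2.07 ± 0.379 in darkness, a change of 5.43 ± 0.62 (SE) with adjusted p = 8.75e-09. The glutathione transferase gene GSTU25 rose by 4.70 ± 0.25 (SE) and AT2G21640 by 2.33 ± 0.41 (SE). AT2G04050 rose by 4.95, CHIL by 4.37 and AT5G51440 by 3.93, the last of which the rule for named genes did not select here and which was followed after its values were seen. MCCA and IVD, genes of leucine breakdown, changed by -1.42 and -1.11. The treatment called 3527 (1722 higher and 1805 lower) probe sets. With a pseudocount of 16 the log2 change was 2.46 for AT2G04050, 2.65 for CHIL and 3.02 for UGT84A1.

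**Figure D2:**
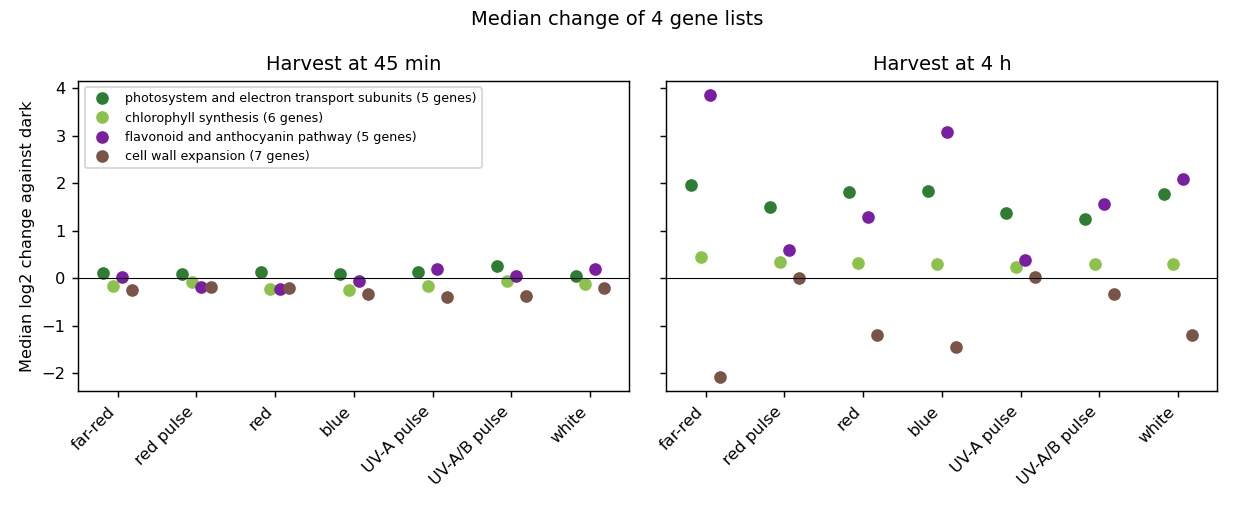
Median log2 change against dark of the 4 gene lists with at least 5 measured members, in each light treatment at 45 min and at 4 h. At 4 h the photosystem medians lie between 1.24 and 1.96 and the cell wall medians reach -2.08 in far-red light.

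All 5 measured genes of the 26 on the photosystem and electron transport list (PSAE-1, PSAN, PSBW, PSBY and ATPC1) rose at 4 h in each of the 7 treatments, and none was called at 45 min by the main fit. Without UV-A/B 45 min replicate 3, PSBW was called higher after UV-A/B at 45 min (0.69, adjusted p = 0.0285). PSAE-1 reached 1163 ± 57.2 in red light against 187 ± 37.3 in darkness, a change of 2.65 ± 0.36 (SE), and PSAN changed by 2.15 ± 0.23 (SE) in far-red light. The list's median change at 4 h was 1.96 in far-red, 1.80 in red, 1.51 after the red pulse, 1.83 in blue, 1.37 after UV-A, 1.24 after UV-A/B and 1.78 in white light. The camera test called the list in all 7, with adjusted p between 1.02e-12 and 6.5e-05. The call was lost with an estimated correlation in far-red light (adjusted p = 0.0648 with an estimated correlation), in blue light (adjusted p = 0.0627) and after UV-A/B (adjusted p = 0.0854), and held in the other 4. Adjusted over the list alone, 5 members were called higher in each treatment. With the replicate number as a block the list was also called at 45 min after UV-A/B (adjusted p = 0.0462). The call of ATPC1 (red pulse) at 4 h was lost without dark 4 h replicate 1 or 3 or red pulse 4 h replicate 1, 2 or 3 (adjusted p = 0.0803, 0.0823, 0.0608, 0.0616 and 0.074). The call of ATPC1 (UV-A) at 4 h was lost without dark 4 h replicate 1 or UV-A 4 h replicate 2 (adjusted p = 0.0527 and 0.0946). The call of PSBY (red pulse) at 4 h was lost without dark 4 h replicate 1 or 3 or red pulse 4 h replicate 2 or 3 (adjusted p = 0.0788, 0.0574, 0.0684 and 0.0764). The call of PSBY (UV-A) at 4 h was lost without dark 4 h replicate 1 or 3 or UV-A 4 h replicate 2 (adjusted p = 0.0903, 0.0587 and 0.194). The call of PSBY (UV-A/B) at 4 h was lost without UV-A/B 4 h replicate 2 (adjusted p = 0.0653).

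Of the 3 measured light harvesting genes, all of which encode CP29 antenna proteins, LHCB4.1 rose in all 7 treatments at 4 h, by 1.00 after UV-A to 1.58 in red light. LHCB4.2 rose in 6 of them, the exception being UV-A/B (0.68, adjusted p = 0.0519), where it had been called at 45 min (0.81). LHCB4.3 rose in far-red and blue light, by 0.86 and 0.55. Over the 14 comparisons with darkness 16 of 42 member tests were called higher and 19 when adjusted over the list alone. Of the 3 Calvin cycle genes RCA rose in all 7 treatments at 4 h, SBPASE rose in the 4 continuous ones, and PRK was not called in any by the main fit, with 11 of 42 member tests called either way. PRK was called in far-red light at 4 h with the replicate number as a block (0.79, adjusted p = 0.0106), although the numbers do not pair these arrays by the rule. A block on the replicate number also called LHCB4.2 (red pulse) at 45 min (adjusted p = 0.0173), LHCB4.2 (UV-A) at 45 min (adjusted p = 0.0275) and LHCB4.2 (UV-A/B) at 4 h (adjusted p = 0.0028). LHCB4.2 (UV-A/B) at 4 h was called with a pseudocount of 16 (adjusted p = 0.0482), under quantile normalization (adjusted p = 0.0426) and without UV-A/B 4 h replicate 1 or 3 (adjusted p = 0.0468 and 0.0209). The call of LHCB4.1 (red pulse) at 4 h was lost without dark 4 h replicate 3 or red pulse 4 h replicate 2 (adjusted p = 0.102 and 0.0648). The call of LHCB4.1 (UV-A) at 4 h was lost under quantile normalization (adjusted p = 0.0522) and without dark 4 h replicate 1, 2 or 3 or UV-A 4 h replicate 1 or 2 (adjusted p = 0.103, 0.0568, 0.211, 0.155 and 0.136). The call of LHCB4.1 (UV-A/B) at 4 h was lost without dark 4 h replicate 3 or UV-A/B 4 h replicate 2 (adjusted p = 0.0526 and 0.138). The call of LHCB4.2 (red pulse) at 4 h was lost without dark 4 h replicate 1 or red pulse 4 h replicate 3 (adjusted p = 0.0513 and 0.0548). The call of LHCB4.2 (UV-A) at 4 h was lost without dark 4 h replicate 1 or 3 or UV-A 4 h replicate 1 or 2 (adjusted p = 0.149, 0.121, 0.0933 and 0.234). The call of LHCB4.2 (UV-A/B) at 45 min was lost without dark 45 min replicate 1 or 3 or UV-A/B 45 min replicate 1 or 2 (adjusted p = 0.11, 0.246, 0.192 and 0.154). The call of SBPASE (red) at 4 h was lost without dark 4 h replicate 1, 2 or 3 or red 4 h replicate 1, 2 or 3 (adjusted p = 0.147, 0.0552, 0.114, 0.0901, 0.131 and 0.082).

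The 6 measured genes of chlorophyll synthesis moved in both directions. CHLM rose at 4 h in far-red, red, blue and white light by 0.82, 0.95, 0.82 and 0.81, while PORB fell in far-red, blue and white light, and GSA1 changed by 0.18 in far-red light with adjusted p = 0.258. Over the 14 comparisons 4 member tests of 84 were called higher and 3 lower, and 12 and 4 when adjusted over the list alone. The list was called lower in blue light at 45 min (adjusted p = 0.0444) and higher after the red pulse at 4 h (adjusted p = 0.0192). Both calls were lost with an estimated correlation, at adjusted p = 0.426 and 0.333, and the first also under quantile normalization (adjusted p = 0.0638). With the replicate number as a block it was also called lower in red light at 45 min (adjusted p = 0.0294). Of the 2 measured carotenoid and photoprotection genes, LYC, for lycopene cyclase, rose at 4 h in far-red light by 0.41 and LIL3:1 by 1.22, and 6 of 28 member tests were called, 10 when adjusted over the list alone. The fit with the replicate number as a block also called CHLI2 (red pulse) at 45 min (adjusted p = 0.0353), CHLI2 (UV-A/B) at 4 h (adjusted p = 0.0175), CHLM (UV-A/B) at 4 h (adjusted p = 0.0046), GSA1 (UV-A/B) at 4 h (adjusted p = 0.0314), HEMB1 (UV-A/B) at 4 h (adjusted p = 0.0124), LIL3:1 (UV-A/B) at 4 h (adjusted p = 0.0342), PORB (blue) at 45 min (adjusted p = 0.0218), PORB (UV-A) at 45 min (adjusted p = 0.00547) and PORB (UV-A/B) at 45 min (adjusted p = 0.0365). The call of CHLM (blue) at 4 h was lost without blue 4 h replicate 2 (adjusted p = 0.0682). The call of CHLM (red) at 4 h was lost without red 4 h replicate 2 (adjusted p = 0.052). The call of CHLM (white) at 4 h was lost without dark 4 h replicate 3 or white 4 h replicate 2 (adjusted p = 0.0626 and 0.0742). The call of LIL3:1 (blue) at 4 h was lost without blue 4 h replicate 1, 2 or 3 or dark 4 h replicate 1, 2 or 3 (adjusted p = 0.11, 0.106, 0.0716, 0.0918, 0.0646 and 0.139). The call of LIL3:1 (far-red) at 4 h was lost without dark 4 h replicate 3 or far-red 4 h replicate 2 (adjusted p = 0.0603 and 0.0622). The call of LYC (red) at 4 h was lost without dark 4 h replicate 1, 2 or 3 or red 4 h replicate 1, 2 or 3 (adjusted p = 0.0565, 0.192, 0.0715, 0.077, 0.18 and 0.0559). The call of PORB (white) at 4 h was lost without dark 4 h replicate 2 (adjusted p = 0.0568).

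Of the flavonoid and anthocyanin genes, all 5 measured members were called higher in far-red light at 4 h, with a median of 3.85. UGT78D1 rose there by 3.88 ± 0.51 (SE), UGT78D2 by 3.85 ± 0.15 (SE), UF3GT by 1.75 and DFR, for dihydroflavonol reductase, by 0.73. In blue, white, UV-A/B and red light 4 of 5 were called higher at 4 h, with medians of 3.08, 2.1, 1.56 and 1.28, and DFR was the member not called in each. The list was called in these 5 treatments with adjusted p between 1.36e-07 and 0.000464, also with an estimated correlation. After the red pulse and UV-A at 4 h 1 and 0 members were called (2 and 3 when adjusted over the list alone), and the list calls were lost with an estimated correlation (adjusted p = 0.0627 and 0.0703). At 45 min UGT78D2 was the 1 member called, in all 7 treatments, by up to 2.70 ± 0.15 (SE) after UV-A/B. The list was then called after UV-A and in white light, also with an estimated correlation, and in far-red, blue and UV-A/B light, where the call was lost with it (adjusted p = 0.0703, 0.0832 and 0.0719). In blue light at 45 min the median of -0.06 and the mean of 0.50 differ in sign, the test following the mean. That was the 1 called test of 120 over the 4 lists in which median, mean and test differed in sign, and 14 tests differed in all. The call of DFR (far-red) at 4 h was lost without dark 4 h replicate 1 (adjusted p = 0.0945). The call of UF3GT (red) at 4 h was lost with a pseudocount of 16 (adjusted p = 0.0588), under quantile normalization (adjusted p = 0.0512) and without dark 4 h replicate 2 or 3 or red 4 h replicate 1 or 3 (adjusted p = 0.127, 0.236, 0.14 and 0.0889). The call of UF3GT (UV-A/B) at 4 h was lost without dark 4 h replicate 3 or UV-A/B 4 h replicate 2 (adjusted p = 0.0851 and 0.0717). The call of UGT78D1 (red) at 4 h was lost without dark 4 h replicate 2 (adjusted p = 0.16). The call of UGT78D1 (UV-A/B) at 4 h was lost without dark 4 h replicate 2 or UV-A/B 4 h replicate 1 or 3 (adjusted p = 0.26, 0.0576 and 0.062). The call of UGT78D2 (red pulse) at 4 h was lost with a pseudocount of 16 (adjusted p = 0.0633) and without dark 4 h replicate 1 or red pulse 4 h replicate 1 or 3 (adjusted p = 0.137, 0.0848 and 0.0924).

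Most measured genes of the cell wall expansion list (7 of 21 members) fell at 4 h in the continuous treatments. In far-red light all 7 measured members were called lower, with a median of -2.08, among them XTH33 at -2.30 ± 0.18 (SE) and EXLA2, an expansin-like gene, at -2.13 ± 0.19 (SE). In blue light all 7 fell (median -1.45), and in red and white light 6 of 7 (medians -1.20 and -1.20). XTH19 changed by -2.93 in blue, -2.42 in white and -1.75 in red light. The list calls had adjusted p between 9.56e-12 and 3.84e-08 and held with an estimated correlation. For the red pulse, UV-A and UV-A/B at 4 h the list was not called, with medians of 0.01, 0.02 and -0.34. At 45 min it was called lower after the red pulse and UV-A and in blue and white light, also with an estimated correlation, and in far-red light, where the call was lost with it (adjusted p = 0.109). Adjusted over the list alone the 14 comparisons held 47 lower and 2 higher member calls of 98, against 41 and 1 over all probe sets. With the replicate number as a block the test also called EXLA2 (red pulse) at 45 min (adjusted p = 0.0325) and EXLA2 (UV-A/B) at 45 min (adjusted p = 0.0213). The 1 higher member call over all probe sets was that of EXLA1 after UV-A/B at 45 min (0.5, adjusted p = 0.0439). The call of EXLA1 (UV-A/B) at 45 min was lost under quantile normalization (adjusted p = 0.06) and without dark 45 min replicate 1 or 3 or UV-A/B 45 min replicate 2 or 3 (adjusted p = 0.06, 0.266, 0.182 and 0.17). The call of EXLA1 (UV-A/B) at 4 h was lost without dark 4 h replicate 2 or UV-A/B 4 h replicate 2 (adjusted p = 0.16 and 0.143). The call of EXLA2 (blue) at 45 min was lost without dark 45 min replicate 2 (adjusted p = 0.0712). The call of EXLA2 (white) at 45 min was lost without white 45 min replicate 1 (adjusted p = 0.0669). The call of EXPA8 (UV-A) at 45 min was lost under quantile normalization (adjusted p = 0.0531) and without dark 45 min replicate 1 or 3 or UV-A 45 min replicate 3 (adjusted p = 0.15, 0.195 and 0.203). The call of EXPA8 (UV-A/B) at 45 min was lost without dark 45 min replicate 1 or 3 or UV-A/B 45 min replicate 1 or 2 (adjusted p = 0.139, 0.172, 0.0613 and 0.305). The call of EXPB1 (UV-A) at 45 min was lost without dark 45 min replicate 1 or 3 or UV-A 45 min replicate 1 or 3 (adjusted p = 0.197, 0.125, 0.201 and 0.118). The call of XTH19 (UV-A/B) at 4 h was lost without UV-A/B 4 h replicate 2 (adjusted p = 0.0545). The call of XTH33 (blue) at 45 min was lost without dark 45 min replicate 2 (adjusted p = 0.0661). The call of XTH33 (red pulse) at 45 min was lost without dark 45 min replicate 1 or 2 or red pulse 45 min replicate 1 or 2 (adjusted p = 0.0564, 0.198, 0.0843 and 0.104). The call of XTH33 (UV-A) at 4 h was lost without dark 4 h replicate 2 or UV-A 4 h replicate 2 (adjusted p = 0.0694 and 0.0556). The call of XTH33 (UV-A/B) at 45 min was lost without dark 45 min replicate 2 (adjusted p = 0.0572). The call of XTH33 (white) at 45 min was lost without dark 45 min replicate 2 or white 45 min replicate 1 (adjusted p = 0.138 and 0.128).

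Smaller lists were read member by member over the 14 comparisons with darkness. Both measured genes linked to PIF factors or shade, IAA29 and HAT2, fell in the continuous treatments at 4 h, with HAT2 at -2.12 ± 0.14 (SE) in far-red light, and 21 of 28 member tests were lower (24 when adjusted over the list alone). Of the auxin responsive genes IAA29, GH3.3 and WES1, 25 of 42 member tests were lower and 1 higher (35 and 1 when adjusted over the list alone), the higher one being GH3.3 after UV-A/B at 45 min, at 698 ± 144 against 309 ± 48.2 (1.16 ± 0.23 (SE)). Of the light signalling genes, HYH was higher in 12 of 14 comparisons, and FHL, which acts in phytochrome A signalling, was lower in 7 and reached -1.33 ± 0.15 (SE) in far-red light at 4 h (14 and 14 of the 28 member tests when adjusted over the list alone). A block on the replicate number also called FHL (blue) at 45 min (adjusted p = 0.0425), GH3.3 (red pulse) at 45 min (adjusted p = 0.016), HAT2 (red pulse) at 45 min (adjusted p = 0.0268), IAA29 (UV-A/B) at 4 h (adjusted p = 0.0466), WES1 (red) at 45 min (adjusted p = 0.0103), WES1 (red pulse) at 45 min (adjusted p = 0.0194), WES1 (UV-A) at 45 min (adjusted p = 0.00622) and WES1 (UV-A/B) at 4 h (adjusted p = 0.00181). The call of FHL (red) at 45 min was lost without dark 45 min replicate 1, 2 or 3 or red 45 min replicate 2 or 3 (adjusted p = 0.0883, 0.0625, 0.217, 0.314 and 0.0689). The call of GH3.3 (red) at 45 min was lost without dark 45 min replicate 1 or 3 or red 45 min replicate 1 or 2 (adjusted p = 0.116, 0.258, 0.186 and 0.324). The call of GH3.3 (UV-A) at 45 min was lost without dark 45 min replicate 3 or UV-A 45 min replicate 2 (adjusted p = 0.0719 and 0.0592). The call of GH3.3 (UV-A/B) at 4 h was lost without dark 4 h replicate 1 or 3 or UV-A/B 4 h replicate 1, 2 or 3 (adjusted p = 0.116, 0.124, 0.0803, 0.103 and 0.0818). The call of HAT2 (far-red) at 45 min was lost without dark 45 min replicate 2 or 3 or far-red 45 min replicate 1 (adjusted p = 0.0639, 0.123 and 0.263). The call of HAT2 (red) at 45 min was lost without dark 45 min replicate 1, 2 or 3 or red 45 min replicate 1 or 2 (adjusted p = 0.0524, 0.115, 0.208, 0.291 and 0.133).

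ICL, the isocitrate lyase gene of the glyoxylate cycle, was called lower at 4 h in 6 treatments, with a change of -1.23 in blue light. After the red pulse its change was -0.77 (adjusted p = 0.0827). With the replicate number as a block ICL was called there too (adjusted p = 9.7e-06), although the numbers do not pair these arrays by the rule. SDP1, a triacylglycerol lipase gene, fell at 4 h in far-red (-0.39), blue (-0.32), UV-A/B (-0.39) and white light (-0.35), and 10 of 28 member tests of that list were lower (13 when adjusted over the list alone). Of the dark inducible genes MCCA, IVD and ATG8E, 12 of 42 member tests were lower (19 when adjusted over the list alone), and ATG8E was called in none by the main fit. In far-red light at 4 h ATG8E was called lower without dark 4 h replicate 3 (-0.47, adjusted p = 0.0203). It was also called there with the replicate number as a block (adjusted p = 0.0478), although the numbers do not pair these arrays by the rule. The only measured clock gene, GI, was higher in 11 of 14 comparisons (12 when adjusted over the list alone) and lower in 1, UV-A at 4 h (-0.64 ± 0.17 (SE)). UGT84A1, the only measured phenylpropanoid gene, was higher in 2, UV-A/B and far-red at 4 h, and GID1A was lower in 1 (2 when adjusted over the list alone), UV-A/B at 4 h (-0.50). The wound and stress list had 5 of 42 member tests higher (6 when adjusted over the list alone), the heat shock list 3 of 42 (4 when adjusted over the list alone), with ATHSP22.0 between -0.24 and 0.25 and not called in any, and the oxidative stress list 2 of 28 (2 when adjusted over the list alone). EXPA18, the measured root marker, was not called in any. The log2 change was -0.33 for GID1A (UV-A/B) at 4 h without dark 4 h replicate 3. The fit with the replicate number as a block also called AT2G29500 (UV-A) at 45 min (adjusted p = 0.0331). The call of AT2G29500 (UV-A/B) at 45 min was lost without UV-A/B 45 min replicate 1 (adjusted p = 0.171). The call of GI (UV-A) at 4 h was lost without dark 4 h replicate 1 or 3 or UV-A 4 h replicate 2 (adjusted p = 0.0611, 0.0577 and 0.147). The call of GID1A (UV-A/B) at 4 h was lost without dark 4 h replicate 3 or UV-A/B 4 h replicate 2 (adjusted p = 0.16 and 0.128). The call of ICL (red) at 4 h was lost without red 4 h replicate 3 (adjusted p = 0.0593). The call of ICL (UV-A) at 4 h was lost without dark 4 h replicate 1 or 2 or UV-A 4 h replicate 1 or 3 (adjusted p = 0.0728, 0.121, 0.0856 and 0.137). The call of IVD (UV-A/B) at 45 min was lost without dark 45 min replicate 3 or UV-A/B 45 min replicate 1 (adjusted p = 0.078 and 0.102). The call of MCCA (UV-A) at 4 h was lost without UV-A 4 h replicate 3 (adjusted p = 0.0609). The call of UGT84A1 (far-red) at 4 h was lost under quantile normalization (adjusted p = 0.0662) and without far-red 4 h replicate 2 or 3 (adjusted p = 0.147 and 0.0682). The call of WRKY6 (blue) at 45 min was lost without blue 45 min replicate 1 or 3 or dark 45 min replicate 1, 2 or 3 (adjusted p = 0.113, 0.297, 0.0734, 0.188 and 0.0787). The call of WRKY6 (UV-A) at 45 min was lost without dark 45 min replicate 2 or UV-A 45 min replicate 3 (adjusted p = 0.0605 and 0.0727).

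**Figure D3:**
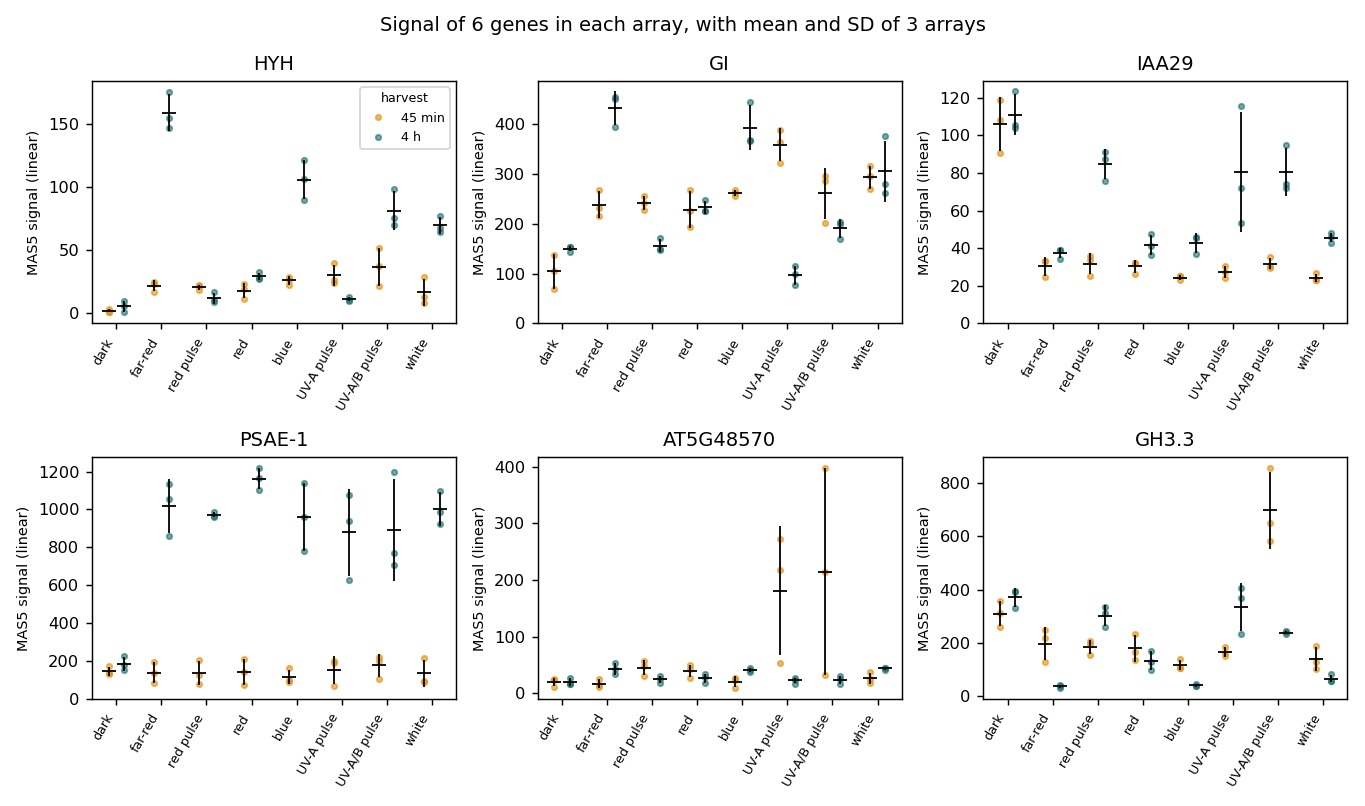
Linear MAS5 signal of 6 genes in the 48 arrays, with each array as a point, the mean as a dash and the SD of 3 arrays as a line, in the dark control and the 7 light treatments at 45 min (orange) and 4 h (green). HYH rises to 159 ± 14.8 in far-red light at 4 h, PSAE-1 rises at 4 h in all 7 treatments, and GH3.3 lies above darkness at 45 min after the UV-A/B pulse, where it is called higher.

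Probe sets called in the same direction in all 7 treatments numbered 160 higher and 46 lower at 45 min and 207 higher and 97 lower at 4 h. Of these, 48 and 18 at 45 min and 74 and 39 at 4 h stand for named genes. The 7 comparisons of a harvest share their 3 dark arrays. In 20 simulations of unchanged groups against shared dark arrays no probe set was called in all 7, and independent lists of the observed sizes would share 6.61e-08 and 4.16e-10 at 45 min and 1.30e-04 and 5.85e-05 at 4 h. The first value leaves out the effects and the second the shared dark arrays, and part of the excess may come from the shared controls, which with 3 arrays were not split.

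Continuous red light was compared with the red pulse. The pulse was given at a higher photon flux than continuous red light, so duration and flux differ together. The comparison therefore cannot separate the effect of lasting light from that of photon flux. At 45 min limma called 0 probe sets between continuous red and the pulse, with 578 at an unadjusted p under 0.05 where 789 are expected by chance. Without red 45 min replicate 3 and under quantile normalization 1 was called. Replicate numbers pair these arrays by the rule (r = 0.161, 0.305 and 0.268), which the main fit leaves out. The shortfall therefore does not show that the treatments are alike. HYH differed by -0.23 ± 0.38 (SE) and IAA29 by -0.05 ± 0.18 (SE). At 4 h continuous red was higher than the pulse for AT1G60590 by 2.14 ± 0.59 (SE), MSRB6 by 2.11 and AT1G64500 by 1.97, and lower for IAA20 (-2.35) and the expansin gene EXPA9 (-1.96). Cell wall genes were lower in continuous red for 6 of 7 members, with a median of -1.04 and adjusted p = 1.49e-17, and flavonoid genes higher for 2 of 5 with adjusted p = 0.00343, and both calls held with an estimated correlation. In all, 645 (281 higher and 364 lower) probe sets were called at 4 h. With a pseudocount of 16 the log2 change was 1.03 for AT1G60590, 1.20 for AT1G64500 and -1.17 for IAA20. The call of AT1G60590 was lost without red 4 h replicate 1, 2 or 3 or red pulse 4 h replicate 2 or 3 (adjusted p = 0.11, 0.0844, 0.0555, 0.0776 and 0.17). The call of CHIL was lost without red 4 h replicate 1 or 3 or red pulse 4 h replicate 1 or 3 (adjusted p = 0.155, 0.166, 0.105 and 0.101).

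The UV-A/B and UV-A pulses were compared to find what the shorter filter cut-off, 307 against 327 nm, adds. The cut-off of 307 nm is given only in the label of UV-A/B 45 min replicate 2. At 45 min GH3.3 was higher after UV-A/B than after UV-A by 2.06 ± 0.23 (SE), AT5G03350 by 2.91 ± 0.56 (SE), the glutaredoxin gene GRX480 by 1.94 and WRKY53 by 1.52. At 4 h UGT84A1 was at 131 ± 16.6 after UV-A/B and 2.0 ± 0.346 after UV-A, a difference of 5.46 ± 0.62 (SE), and AT2G04050 (5.72), GSTU25 (4.28), AT5G51440 (3.42) and CHIL (3.06) were also higher after UV-A/B. Flavonoid genes were higher for 2 of 5 members at 4 h (adjusted p = 1.75e-05) and cell wall genes for 1 of 7 at 45 min (4 when adjusted over the list alone; adjusted p = 0.00125), and both list calls held with an estimated correlation. Counts were 341 (218 higher and 123 lower) at 45 min and 1379 (751 higher and 628 lower) at 4 h. The first became 203 without UV-A/B 45 min replicate 3, 227 without UV-A/B 45 min replicate 2 and dark 4 h replicate 1, and 98 in a fit on the 2 groups alone, and the second 472 in such a fit. The description of UV-A/B 45 min replicate 2 gives darkness. The log2 change with a pseudocount of 16 was 2.58 for AT2G04050, 1.67 for AT5G03350, 3.03 for UGT84A1 and 1.01 for WRKY53. The fit with the replicate number as a block also called EXLA2 (adjusted p = 0.0195). The call of EXLA1 was lost under quantile normalization (adjusted p = 0.0513) and without UV-A 45 min replicate 1 or 3 or UV-A/B 45 min replicate 2 or 3 (adjusted p = 0.14, 0.197, 0.18 and 0.198).

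Between red and far-red light, 20 probe sets were called at 45 min, all higher in red. They include AT3G14200 at 1.88 ± 0.27 (SE) and AT2G20560 at 1.46 ± 0.24 (SE), both of the DnaJ chaperone family, and the HSP70 gene AT3G09440 at 0.88. At 4 h flavonoid genes were lower in red than in far-red light for 4 of 5 members (5 when adjusted over the list alone), with a median of -2.06 and adjusted p = 5.33e-11, and cell wall genes were higher for 6 of 7, with a median of 1.09 and adjusted p = 2.95e-13; both calls held with an estimated correlation. AT3G52740 changed by -4.33 in red against far-red light, CHIL changed by -3.38 ± 0.44 (SE), HYH by -2.40, and GH3.3 was higher in red by 1.84 ± 0.23 (SE). The count at 4 h was 1156 (567 higher and 589 lower), and a fit on the 2 groups alone called 9 at 45 min. With a pseudocount of 16 the log2 change was -2.26 for AT3G52740. The call of AT3G09440 was lost without red 45 min replicate 1 (adjusted p = 0.0923). The call of EXLA2 was lost without far-red 4 h replicate 1 or 3 or red 4 h replicate 3 (adjusted p = 0.0683, 0.076 and 0.0591).

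Blue light was compared with red light at equal photon flux. At 45 min AT3G14200 was lower in blue (-1.32 ± 0.27 (SE)), as was HAT2 (-0.82 ± 0.14 (SE)), and AT2G38100 was higher by 1.13. At 4 h AT3G52740 was higher in blue by 3.32 ± 0.63 (SE), CHIL by 2.31 and MSRB6 by 1.86, while GH3.3 changed by -1.71 ± 0.23 (SE). Flavonoid genes were higher in blue for 3 of 5 members at 4 h (4 when adjusted over the list alone), with a median of 1.41 and adjusted p = 6.6e-08, and cell wall genes lower for 4 of 7 (6 when adjusted over the list alone), with a median of -0.68 and adjusted p = 1.35e-08, and both held with an estimated correlation. At 45 min the cell wall call of adjusted p = 0.0121 was lost with an estimated correlation (adjusted p = 0.107). Counts were 81 (11 higher and 70 lower) at 45 min and 655 (339 higher and 316 lower) at 4 h, and with the replicate number as a block 144 and 1012. The first became 47 without red 45 min replicate 2, 53 without red 45 min replicate 3 and 31 in a fit on the 2 groups alone, and the second 420 without blue 4 h replicate 1. The log2 change with a pseudocount of 16 was 0.63 for AT2G38100 and 1.48 for AT3G52740. The fit with the replicate number as a block also called XTH18 (adjusted p = 0.0225). The call of AT2G38100 was lost without red 45 min replicate 2 (adjusted p = 0.0874). The call of AT3G14200 was lost without blue 45 min replicate 3 or red 45 min replicate 3 (adjusted p = 0.103 and 0.0658). The call of UF3GT was lost without blue 4 h replicate 1 or 3 or red 4 h replicate 2 or 3 (adjusted p = 0.186, 0.288, 0.202 and 0.0943).

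Whether a light effect differed between the harvests was tested as the 4 h effect minus the 45 min effect. After the pulses the effects on GI and IAA29 differed: for GI the difference was -1.21 ± 0.23 (SE) for the red pulse, -2.47 ± 0.23 (SE) for UV-A and -1.01 ± 0.23 (SE) for UV-A/B, and for IAA29 it was 1.33, 1.38 and 1.23. AT5G48570 differed by -2.68 ± 0.76 (SE) for UV-A. In far-red light the effect grew for CHIL by 5.62 ± 0.62 (SE) and HYH by 1.86 ± 0.54 (SE). AT5G58750 had a lower effect at 4 h in each of the 7 treatments, by -4.19 in far-red light. The photosystem list was called in all 7 treatments and its medians lay between 0.88 and 1.72, and the list call was lost with an estimated correlation in far-red (adjusted p = 0.0612), UV-A (adjusted p = 0.0818) and UV-A/B light (adjusted p = 0.229). Cell wall genes had lower effects in far-red light at 4 h (median -1.83, adjusted p = 7.77e-13) and flavonoid genes gained there (median 2.04, adjusted p = 7.74e-08), with both calls holding with an estimated correlation. With a pseudocount of 16 the log2 change was -2.0 for AT5G58750 (far-red). The log2 change was 1.20 for HYH without dark 4 h replicate 3. The call of AT5G48570 was lost without dark 45 min replicate 3, dark 4 h replicate 2, UV-A 45 min replicate 1 or 2 or UV-A 4 h replicate 3 (adjusted p = 0.0993, 0.0908, 0.116, 0.0945 and 0.0736). The call of HYH was lost without dark 45 min replicate 1 or dark 4 h replicate 3 (adjusted p = 0.0579 and 0.0987).

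The difference between harvests was called for 2367 probe sets in far-red, 1798 in blue, 1584 after UV-A/B, 1377 in white, 1073 in red, 658 after UV-A and 271 after the red pulse. A fit on the 4 groups concerned called 918 for UV-A/B and 362 for UV-A. The counts of the red pulse, red and UV-A rose with the replicate number as a block, as given in the part on processing. Between the dark arrays of 4 h and 45 min 5 probe sets were called, all higher at 4 h and none with a gene listed here. They include 250429_at at 2.57 and 263345_s_at at 1.70, chosen after their values were seen. That count became 2 without dark 4 h replicate 1, 8 without dark 4 h replicate 3, 18 without dark 45 min replicate 1, 2 without dark 45 min replicate 2, 1 without dark 45 min replicate 3, 3 with a pseudocount of 16 and 2 in a fit on the 2 groups alone. It rose with the replicate number as a block, which does not pair these arrays by the rule, as given in the part on processing.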

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

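The tests of the difference between harvests were planned before the data were examined; the 4 weighings of technical explanations in this part were chosen after their patterns were seen, the 2 on chaperone genes after first choices had proved uninformative or lenient. The difference between the 4 h and 45 min effects was tested for 9 panel genes in 7 treatments, and 16 of 63 tests had a limma adjusted p under 0.05 over all probe sets. More of them were called with the replicate number as a block, as given in the part on processing. In far-red light the 4 h effect was larger for LHCB4.1 by 1.22, SBPASE by 1.71, DFR by 1.11 and HYH by 1.86. In red light that of LHCB4.1 was larger by 1.63 and in blue light that of SBPASE by 1.68. After the red pulse GI differed by -1.21 and IAA29 by 1.33. After UV-A HYH differed by -2.29, GI by -2.47 and IAA29 by 1.38. After UV-A/B GI differed by -1.01, IAA29 by 1.23 and WRKY53 by -1.39. In white light LHCB4.1 differed by 1.3 and IAA29 by 0.81. The log2 change with a pseudocount of 16 was -1.0 for HYH (UV-A). The log2 change was 1.20 for HYH (far-red) without dark 4 h replicate 3. The fit with the replicate number as a block also called LHCB4.1 (UV-A/B) (adjusted p = 0.0207). The call of HYH (far-red) was lost without dark 45 min replicate 1 or dark 4 h replicate 3 (adjusted p = 0.0579 and 0.0987). The call of IAA29 (white) was lost with a pseudocount of 16 (adjusted p = 0.0713) and without dark 45 min replicate 2 or 3, dark 4 h replicate 1 or 2, white 45 min replicate 1 or 2 or white 4 h replicate 1 or 2 (adjusted p = 0.0971, 0.0611, 0.0752, 0.0747, 0.0717, 0.0625, 0.06 and 0.0767). The call of LHCB4.1 (far-red) was lost under quantile normalization (adjusted p = 0.0505) and without dark 45 min replicate 1 or 2, dark 4 h replicate 1 or 3, far-red 45 min replicate 1 or 3 or far-red 4 h replicate 1, 2 or 3 (adjusted p = 0.0592, 0.143, 0.0642, 0.127, 0.0799, 0.143, 0.0533, 0.0759 and 0.0936). The call of LHCB4.1 (red) was lost without dark 45 min replicate 2 or red 45 min replicate 3 (adjusted p = 0.0529 and 0.0515). The call of LHCB4.1 (white) was lost under quantile normalization (adjusted p = 0.0538) and without dark 45 min replicate 1 or 2, dark 4 h replicate 1 or 3, white 45 min replicate 1 or 3 or white 4 h replicate 1 or 2 (adjusted p = 0.0674, 0.155, 0.0745, 0.14, 0.132, 0.118, 0.105 and 0.0993). The call of SBPASE (blue) was lost without blue 45 min replicate 3, blue 4 h replicate 2, dark 45 min replicate 1 or 2 or dark 4 h replicate 1 or 3 (adjusted p = 0.0934, 0.0857, 0.0552, 0.0767, 0.0624 and 0.0505). The call of SBPASE (far-red) was lost without dark 45 min replicate 2 or far-red 45 min replicate 3 (adjusted p = 0.0569 and 0.0657). The call of WRKY53 was lost without dark 4 h replicate 2, UV-A/B 45 min replicate 3 or UV-A/B 4 h replicate 1 (adjusted p = 0.0835, 0.0522 and 0.0675).

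Chaperone and co-chaperone genes (AT5G48570, AT2G29500, AT5G51440, Hop3 and AT2G20560, chosen because their values after the UV pulses were high) had a median change of 2.79 at 45 min after UV-A/B and 2.69 after UV-A, while ATHSP22.0 of the heat shock list changed by 0.19 and 0.25 (adjusted p = 0.727 and 0.725). Handling or warming shared by all light treatments is argued against, since the median of the 5 genes was -0.049 in far-red light, where their changes lay between -0.225 and 0.236, while it was -0.017 in blue and 0.646 in white light, where AT2G20560 was called higher (1.19, adjusted p = 0.00112). Handling or warming that differed between treatments was not tested and stays open. Handling shared by the pulses and UV light cannot be told apart here, since each UV treatment was a pulse and the median was 1.687 after the red pulse, where AT2G20560 (1.77, adjusted p = 2.07e-06), Hop3 (1.74, adjusted p = 0.00604) and AT5G51440 (1.69, adjusted p = 0.0366) were called, but also 1.301 in continuous red light, where AT2G20560 (1.47, adjusted p = 6.79e-05) and Hop3 (1.43, adjusted p = 0.0382) were called. The call of Hop3 in red light was lost with a pseudocount of 16 (adjusted p = 0.113) and without dark 45 min replicate 2 or 3 or red 45 min replicate 1, 2 or 3 (adjusted p = 0.105, 0.252, 0.132, 0.179 and 0.0555), its call after the red pulse without dark 45 min replicate 3 (adjusted p = 0.0691), and that of AT5G51440 after the red pulse with a pseudocount of 16 (1.03, adjusted p = 0.0725) and without dark 45 min replicate 2 or 3 or red pulse 45 min replicate 1, 2 or 3 (adjusted p = 0.216, 0.0709, 0.129, 0.0781 and 0.0971). The medians of UV-A/B minus dark within replicates 1, 2 and 3 were 3.59, 3.04 and 1.75, and for AT2G29500, whose call was lost without UV-A/B 45 min replicate 1 (0.94, adjusted p = 0.171), the differences were 3.55, 1.55 and 0.34, so that what sets the size stays open, as does a response to UV light as a hypothesis.

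The description of UV-A/B 45 min replicate 2 gives darkness. Over the 1084 probe sets called between UV-A/B and dark without this array, its median position between dark (0) and UV-A/B (1) was 1.008, while the dark arrays lay between -0.014 and 0.025. A dark sample in its place is argued against by this value, and the array was kept as UV-A/B.

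AT1G72290 was lower than dark 4 h in all 7 treatments at 4 h. A high level in the shared dark 4 h arrays is argued against, since the smallest fall against the dark 45 min arrays was -4.49. The light-treated signal lies near the floor, and a pseudocount of 16 gives -2.06 to -2.12, so the size of the fall is open. A light response may underlie it, a hypothesis found and tested on these data.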

How the results depend on the processing

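No called result reversed under the alternatives run, and counts not named here stayed within 1.5 times their main value. Of the alternatives, only the setting without UV-A/B 45 min replicate 2 and dark 4 h replicate 1 was chosen after the data were seen. The rule that made the UV-A/B time difference paired was also set after blocked calls had been seen. Blocked counts had been seen before the pairing rule was applied. The cause of each change was not tested, except that fits on fewer arrays have fewer residual degrees of freedom. Fits on the groups compared alone called 179 for far-red 45 min, 197 for the red pulse 45 min, 717 for the red pulse 4 h, 214 for red 45 min, 406 for blue 45 min, 482 for UV-A 45 min, 409 for UV-A 4 h, 785 for UV-A/B 45 min, 303 for white 45 min, 98 and 472 for UV-A/B against UV-A at 45 min and 4 h, 9 for red against far-red 45 min, 31 for blue against red 45 min, 362 and 918 for the time difference of UV-A and UV-A/B, and 2 for the dark groups. With the replicate block the paired contrasts moved for the red pulse 45 min (532), blue against red 45 min (144) and blue against red 4 h (1012), and of the list calls the chlorophyll list in red light at 45 min and the photosystem list after UV-A/B at 45 min were gained; the block changed no other list call of a paired contrast and moved no other count of one by over 1.5 times. Of 1001 pairs of a listed or named gene and a paired contrast (the UV-A/B time difference included), it added 37 calls and ended 1, that of AT2G04050 in the UV-A/B time difference (5.09, adjusted p = 0.0629 against 0.0372). Where the numbers do not pair the arrays by the rule (17 contrasts, 11 of them of 2 groups, in 9 of which each array correlated best with its own number), it added 76 calls and ended 0 of 1480 such pairs, the call of ICL after the red pulse at 4 h (adjusted p = 9.7e-06) being one of those added, and gave 794 for the red pulse 4 h, 1288 for UV-A 4 h, 520, 1696 and 1099 for the time difference of the red pulse, red and UV-A, and 35 for the dark groups. Without UV-A/B 45 min replicate 2 and dark 4 h replicate 1 the counts were 266 for the red pulse 4 h, 471 for UV-A 4 h, 227 for UV-A/B against UV-A 45 min and 2 for the dark groups. Quantile normalization gave 1 for red against the red pulse 45 min and moved the median of all probe sets by at most 0.037, and a pseudocount of 16 gave 3 for the dark groups. Leaving out each array in turn gave 223 to 314 for the red pulse 4 h, 463 to 651 for UV-A 4 h, 0 to 1 for red against the red pulse 45 min, 203 to 341 for UV-A/B against UV-A 45 min, 47 to 61 for blue against red 45 min, 420 to 540 for blue against red 4 h, and 1 to 18 for the dark groups. With an estimated correlation the photosystem list was called in 4 light against dark contrasts (of 7 called) and 4 time contrasts (of 7), the chlorophyll list in 0 (of 2) and 0 (of 4), and the flavonoid list in 7 (of 12) and 3 (of 5). With the block the chlorophyll list was called in 5 light against dark contrasts and the photosystem list in 1 between lights, under quantile normalization the chlorophyll list in 1, and 16 panel tests of the time family became 29 with the block. Of 1197 named gene and contrast pairs, 44 lost the call under an alternative other than leaving out 1 array, 355 without some 1 array, and 0 reversed; a pseudocount of 16 moved 285 by over 1.5 times. Signals near the floor limit what can be said of low genes.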

Other observations

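The lists in this part were made from the annotation before any expression result was seen; the counts of other splits were planned, and the diagnostic on intact light arrays was chosen after its counts were seen. The auxin or IAA family (8 measured genes) was called lower by camera in 9 of 30 contrasts, of which 7 held with an estimated correlation. At 45 min its median was -0.30 in far-red (adjusted p = 0.000165), -0.31 in blue (adjusted p = 0.000417), -0.26 in red (adjusted p = 0.00103), -0.43 in white (adjusted p = 2.11e-05) and -0.22 after the red pulse (adjusted p = 0.00779), and these 5 held with an estimated correlation, as did red at 4 h (adjusted p = 0.0419 with it) and red against the red pulse at 4 h (adjusted p = 0.00576 with it). Of its members, only IAA29 was called by limma at 45 min in far-red light and after the red pulse. In blue, red and white light at 45 min only IAA29 and GH3.3 were. Both genes are also on the auxin responsive list above, so the 2 lists are not independent. The calls after UV-A at 45 min (adjusted p = 0.149 with an estimated correlation) and in white light at 4 h (adjusted p = 0.101) did not hold.

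Nuclear genes named for photosystems, chlorophyll or light harvesting (19 measured) were called higher in all 7 treatments at 4 h, with medians of 1.14 in far-red, 0.94 in blue, 0.92 in white, 0.79 in red, 0.57 after the red pulse, 0.48 after UV-A/B and 0.47 after UV-A. None of its 13 calls held with an estimated correlation (adjusted p = 0.661 in far-red light at 4 h). Plastid-encoded photosynthesis genes (35 measured) had at most 1 member called higher and 1 lower in a contrast, with medians between -0.39 and 0.19, and its 2 calls did not hold with an estimated correlation. The plastid-encoded transcription and translation list had 3 calls, tubulins 10, expansins 7, UGT glycosyltransferases 6, XTH genes 3, BGLU genes 2, GSTU genes 1 and CML genes 1, none of which held with an estimated correlation. Expansins moved both ways, with at most 5 members called higher and 7 lower in a contrast, as did XTH genes, with at most 2 higher and 4 lower. The lists of plastid-encoded NADH dehydrogenase-like, SCPL, cytochrome P450, TBL, SWEET, tetraspanin, histone, WRKY, autophagy, RNA editing and mitochondrially encoded genes were called in 0 of 30 contrasts, and cold regulated COR genes (3 measured) were too few for the test. Of the 660 tests of these lists, 133 had a median, mean and test that differed in sign, 0 of them called.

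For each comparison of 3 arrays against 3 the 10 splits of the 6 arrays are too few for a share under 0.05. The count of the real split was reached by 1 of the 10 splits in each such comparison, the real split itself, except red against the red pulse at 45 min, where all 10 gave 0. The real count and the highest of the other splits were, for light against dark, far-red 45 min (329, 5), far-red 4 h (4584, 0), red pulse 45 min (348, 11), red pulse 4 h (430, 0), red 45 min (368, 1), red 4 h (2541, 1), blue 45 min (643, 1), blue 4 h (4169, 0), UV-A 45 min (899, 13), UV-A 4 h (742, 0), UV-A/B 45 min (1426, 6), UV-A/B 4 h (3527, 0), white 45 min (521, 35), white 4 h (3355, 0), and between lights, red against red pulse 45 min (0, 0), red against red pulse 4 h (645, 1), UV-A/B against UV-A 45 min (341, 30), UV-A/B against UV-A 4 h (1379, 234), red against far-red 45 min (20, 0), red against far-red 4 h (1156, 1), blue against red 45 min (81, 1), blue against red 4 h (655, 0). For the dark groups they were 5 and 1. After UV-A/B against UV-A at 4 h the split that gave 234 did not part all same-numbered pairs, and the splits that parted all pairs gave at most 1. In the paired comparisons the splits parting all pairs gave at most 2.

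For the difference between harvests 100 splits were drawn per treatment. Splits that called as many probe sets as the real one, it included, numbered 3 of 100 for far-red (2367 real, 2403 highest other), 4 of 100 for red pulse (271 real, 416 highest other), 1 of 100 for red (1073 real, 1025 highest other), 6 of 100 for blue (1798 real, 2364 highest other), 4 of 100 for UV-A (658 real, 833 highest other), 3 of 100 for UV-A/B (1584 real, 1759 highest other), 7 of 100 for white (1377 real, 1965 highest other). This count cannot decide whether chance gave the real values in any treatment, since some draws keep the light arrays of each harvest together. In each treatment 8 of the draws left the light arrays of both harvests intact, so that they keep a real time difference, and every other split as large was among these 8. The highest count without intact light arrays was 1 for far-red, the red pulse, red, blue and white, 5 for UV-A and 2 for UV-A/B. These counts point to a structure of the samples, the harvest time, in the splits that came out large.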
